A study of Mus musculus with 2 samples.

How the data were processed

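Chromatin immunoprecipitation with an antibody against H3K27ac was followed by sequencing in 2 biological replicates of mouse embryonic heart at embryonic day 14.5, per the labels. Each replicate came from pooled embryos of both sexes of the strain B6NTac;B6NCrl/Lap. Both replicates form 1 group, taken from the labels with their replicate numbers. The labels name the same donor record for both, so differences between them measure the spread between these pools of embryos and libraries.

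The deposited data used here were 4 peak lists in narrowPeak format on the mouse build mm10, per the file headers. The authors called peaks on each replicate alone, from its filtered alignments and 1 further file, per the deposited file descriptions. The pooled list was called by the authors on the alignments of both replicates together. The replicated list was derived by the authors from the pooled list and both single lists, and the rule of that selection is not given in the sources used here. The peak caller and its threshold are not given in the sources used here either. The lowest −log10 p of the deposited lists was 2.04 in replicate 1, 2.05 in replicate 2, 2.13 in the replicated list and 2.01 in the pooled list. Each deposited peak has a signal value, whose scale is not stated in the headers, and the −log10 of its p-value and of its q-value as the authors' peak caller gave them. The signal value of a peak is the authors' own and was used only to describe, rank or filter peaks within its own list. A −log10 q of at least 2 was found for 84.5% of the peaks of replicate 1, 80.4% of replicate 2, 99.5% of the replicated list and 92.4% of the pooled list. The design fixed beforehand spoke of fold enrichment for the signal value, and the text keeps the wider term because the scale is not stated. Peak lists hold no read counts, so the depth per sample is unknown and no counting interval was given. Signal tracks and alignments were not used here.

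Gene positions came from the GENCODE vM21 annotation and sequence from GRCm38.p6, which shares its chromosome coordinates with mm10. No peak ran past the end of a chromosome, and 5 to 6 peaks per list lay on unplaced sequences and were left out of gene and sequence comparisons. The background was 21938 protein-coding genes with 54446 distinct transcript starts on chromosomes 1 to 19, X and Y. All genes of the fixed lists were matched by symbol. The symbol Aldoa belongs to several genes, of which the longest was used.

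A peak counted as shared when at least 50% of it, or of the peak it overlapped, was covered. Chance placement was described by 100 circular shifts of the other list along each chromosome. A promoter was the sequence within 1 kb of a protein-coding transcript start, and peaks outside all promoters were distal. A gene's promoter signal value was that of its strongest promoter peak. One peak can reach the promoters of several genes, as for 2578 of the 11802 genes with a replicated promoter peak. The 21 gene lists, drawn from general knowledge of marker genes, were cardiac transcription factors, sarcomere, cardiac calcium handling and conduction, fetal cardiac hormones and stress genes, endocardium and endothelium, epicardium, cardiac fibroblasts and valve mesenchyme, smooth muscle and pericytes, erythroid cells, and macrophages and leukocytes. The others were cardiac neural crest with neurons and glia, cell cycle, mitochondrial energy metabolism, glycolysis, housekeeping, skeletal muscle, liver, forebrain, lung and gut epithelium, limb and posterior patterning, and pluripotency and germline. Promoter shares of the lists were compared with all other genes by Fisher's exact test (two-sided, Benjamini-Hochberg over lists, threshold 0.05). Breadth was the length covered by replicated peaks within 10 kb of any transcript start of a gene, as log10 after adding 100 bases. The list mean was compared with 100000 random draws of as many genes with a promoter peak (two-sided permutation test). The mean number of distal peaks within 50 kb of the 5′ end was compared in the same way. Strength and width of promoter and distal peaks were compared as per-chromosome log2 ratios of medians with 100000 sign permutations. Distal peaks with gaps of at most 12.5 kb were joined into clusters, and the 1% with the most covered bases were examined. Lists were tested for a gene 5′ end within 50 kb of such a cluster with Fisher's exact test.

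Site densities of 18 consensus sequences (17 distinct, since HAND and NEUROD are reverse complements) were counted on both strands in distal replicated peaks. They were compared with regions of the same length 10 kb away on both sides that overlapped no peak of the pooled or replicated list. At least 90% of a control region had to be known sequence, and 0.5 was added to site counts. This left 45221 peaks and 75930 control regions. Per-chromosome log2 ratios were tested by 100000 sign permutations, and the reversed sequence served as a control for composition. The reversed RFX sequence had no site and gave no value.

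The gene lists, consensuses, tests, alternatives and the rule for named genes were chosen before the data were examined. Under that rule the text names the 3 members of each list with the strongest promoter peak and up to 3 members without one, in alphabetical order. Further named genes were the 10 with the strongest promoter peaks shared with both replicates, the 10 with the most covered bases, those nearest to the 10 largest clusters, and a fixed set of heart and control genes. Alternatives covered the overlap rule, stricter peak thresholds, the promoter window (500 bp and 2.5 kb), gene 5′ ends only, the pooled list, each single list in place of the replicated list, other distances, other background genes, other joining distances, and other control regions. The setting without replicate 1 is the list of replicate 2 alone, and the reverse. A breadth window of one size around the 5′ end and, for promoter shares, the use of only the replicated peaks shared with both single lists were added after seeing the data. The same restriction for site densities was planned. The limits that decide which lists and consensuses a figure shows were also set after seeing the data. No split of the samples into other groups was run, and no sample was tested as an outlier, since the group has 2 samples.

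Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1, with random seed 7. The code was tested on simulated data, for the first time after a first run on the deposited lists. Overlaps differed from bedtools for 0 of 6000 simulated peaks. Of 100 planted lists 97% were called by the promoter test and 94% by the breadth test, and of 320 lists with no difference 0.625% and 1.56%. A planted consensus was recovered at a log2 ratio of 3.41 against 3.49 expected over 1575 simulated peaks. Sign permutations with no difference gave 2.5% of 400 p-values under 0.05.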

Results

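Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in hearts of mouse embryos at embryonic day 14.5. The group held 2 biological replicates, each made from hearts of pooled embryos of both sexes. The list of replicate 1 held 98096 peaks with a median width of 388 bp, and that of replicate 2 held 107682 peaks with a median width of 329 bp. Peaks called on both replicates together numbered 103625 (pooled list), and the authors' list of replicated peaks held 64342 with a median width of 764 bp. Replicated peaks covered 69.6 Mb, or 2.55% of the chromosomes. Read depth is unknown, since peak lists hold no read counts, and the replicated list is 1 list without a replicate error of its own. With 1 group there was no contrast between conditions, so the comparisons asked how far the replicates gave the same acetylated regions, and which genes and sequences those regions held.

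Promoters of heart muscle genes carried peaks in both replicates. The promoter peak of Myh7, the beta myosin heavy chain gene, had a signal value of 45.4 in replicate 1 and 46.3 in replicate 2, each on the scale of its own list. Gata4 and Nkx2-5, which encode core cardiac transcription factors, had promoter peaks of 34.5 and 28.8 in replicate 1 and of 39.4 and 21.7 in replicate 2. Tnnt2, the cardiac troponin T gene, had 28.5 and 36.1, and Actc1, the cardiac actin gene, had 35.9 and 28.2. The promoter peak of Isl1, a factor of early cardiac progenitors, was found in replicate 2 (5.94) and not in replicate 1, although a weak peak of 280 bp stood in the replicated list (4.27). Of 21938 protein-coding genes, 11587 had a promoter peak in both replicates, 479 in replicate 1 only, 576 in replicate 2 only and 9296 in neither.

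Of the peaks of replicate 1, 60.1% were shared with replicate 2, and 61.0% of the peaks of replicate 2 were shared with replicate 1, with sharing defined as an overlap of at least 50% of either peak. Lists shifted along the chromosomes 100 times gave means of 3.52% and 3.35%, with highest values of 4.29% and 3.81%. The base-pair Jaccard index was 0.553, against a highest shifted value of 0.0161. Sharing followed peak strength. In the strongest decile by signal value only 1 peak of replicate 1 and 4 peaks of replicate 2 were not shared, while 34.6% and 35.5% of the weakest decile were shared. Peaks at promoters were shared more often (81.6% and 83.2%) than distal peaks (55.3% and 56.0%), and shared peaks were wider, with medians of 640 bp against 255 bp in replicate 1 and 502 bp against 226 bp in replicate 2. The rule itself favours wide peaks, since a wide peak counts as shared where it covers at least 50% of a narrow one. Promoter peaks were also wider and stronger than distal ones in both single lists. Sharing was not compared at like width or strength. The shares of all peaks moved with the overlap rule, to 41.2% and 37.5% when at least 50% of both peaks had to be covered. Of the replicated peaks, 85.7% were shared with both single lists, and 62.1% of the pooled peaks were in the replicated list.

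**Figure D1:**
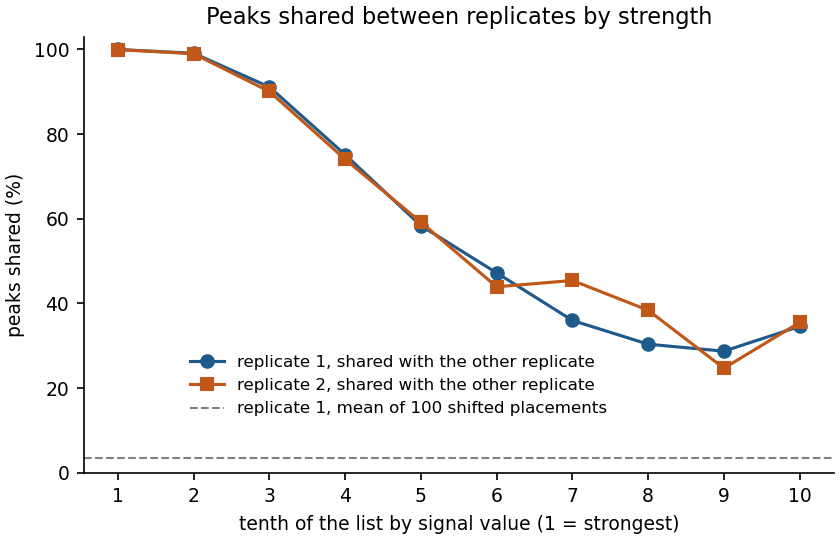
Percent of peaks shared with the other replicate (y axis) in deciles of each replicate's own list ranked by signal value (x axis). The strongest decile is at the left. Circles stand for replicate 1 and squares for replicate 2. The dashed line marks the mean percent of replicate 1 peaks shared with shifted lists of replicate 2 (3.52%). Sharing lay at 99.99% and 99.96% in the strongest decile and at 28.7% and 24.7% in the ninth.

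The strongest promoter peaks included genes that are used in many cell types. Actb, the cytoplasmic beta actin gene, had the highest signal value of the replicated list, followed by Kmt5b, a histone H4 lysine methyltransferase gene, with 73.6. A single peak of 72.7 on chromosome 2 lay over the adjoining starts of Zc3h6 and Gm10762. Klf7, which encodes a Krüppel-like factor, had 72.4, Arrdc3 had 71.9, and Arid1a, a subunit gene of the BAF chromatin remodelling complex, had 70.9. Kansl1 (69.9), Dyrk1a and Erbin (66.1 each) completed the 10 genes with the strongest promoter peaks shared with both replicates.

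Promoter peaks made up 22.8% of the replicated list, 14655 peaks against 49682 distal ones, where shifted lists gave at most 4.23%. By peak summit, 47.5% lay in introns, 28.2% in intergenic sequence, 21.4% within 1 kb of a transcript start, 1.44% in coding exons and 1.52% in untranslated exons. Promoter peaks had a median signal value of 9.70 against 4.47 for distal peaks, a mean log2 ratio of 1.13 ± 0.10 (SD over 20 chromosomes). They were also wider, 1127 bp against 690 bp (log2 0.72 ± 0.11). Both differences had the same direction on 20 of 20 chromosomes (two-sided sign permutation p = 1e-05, the smallest that the permutations can give). Chromosomes are parts of the same peak list, so these p-values and SDs do not measure the spread between replicates. A peak that touches a promoter by any base counts as a promoter peak, so the definition itself favours wide peaks. By summit, the median width was 1109 bp within 1 kb of a transcript start, 702 bp in introns, 691 bp in intergenic sequence, 675 bp in untranslated exons and 649.5 bp in coding exons. The promoter share was 35.6% among replicated peaks with a signal value at or above the median. A replicated promoter peak was found at 11802 genes, or 53.8% of protein-coding genes.

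Genes of heart muscle, endothelium and valve mesenchyme had promoter peaks almost throughout. All 25 cardiac transcription factor genes had one (100% against 53.7% of other genes), led by Mef2a with a signal value of 53.4, Gata4 with 50.6 and Mef2d with 49.3. Others of this list were Nkx2-5 (31.1), Hey2 (22.1), Tbx5 (13.9) and Isl1 (4.27). All 25 sarcomere genes had one as well, led by Myh7 (55.8), Myom1, which encodes an M-line protein (52.1, a peak that also reaches another gene's promoter), and Tnni1, the slow skeletal troponin I gene used in the fetal heart (43.8). Actc1 had 41.6, Tnnt2 30.8 and Myh6, the alpha myosin heavy chain gene, 20.2. Of the calcium handling and conduction genes, 19 of 21 had a promoter peak, with the highest values at Camk2d (46.6), the calcium pump gene Atp2a2 (46.2) and the sodium-calcium exchanger gene Slc8a1 (43.6), while Sln and Hcn1 had none. All 22 endothelial genes had one, with Eng at 17.0, Tek at 14.6, Esam at 14.4 and Pecam1 at 13.3. All 17 genes of fibroblasts and valve mesenchyme had one, with Vcan, a matrix proteoglycan gene, at 21.2, Fn1 at 16.9 and Fbln2 at 14.6.

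These shares passed Fisher's exact test (two-sided, Benjamini-Hochberg over 21 lists). The adjusted p was 3.22e-06 for cardiac transcription factors and for sarcomere genes, 0.000902 for calcium handling and conduction, 1.2e-05 for endothelium and 7.43e-05 for fibroblasts and valve mesenchyme. Lists of general cell functions were higher than other genes too. All 21 genes of mitochondrial energy metabolism had a promoter peak (adjusted exact p = 1.2e-05), with Cpt1b, the muscle carnitine palmitoyltransferase gene, at 42.0, Ppargc1a at 34.3 and Atp5a1 at 31.4 in a peak that also reaches another gene's promoter. All 19 glycolysis genes (adjusted exact p = 2.81e-05) had one, with Gapdh at 48.0, Pfkl at 47.7 and the glucose transporter gene Slc2a1 at 41.6, and so did all 19 housekeeping genes (adjusted p = 2.81e-05), with Actb, Gapdh and Ywhaz (47.7) on top. Of the cell cycle genes 16 of 18 had one (adjusted exact p = 0.00424), with Cdk1 at 22.3, Mcm6 at 21.5 and Cdc20 at 19.4, while Bub1 and Mcm3 had none. Genes are not independent replicates, so these p-values describe the lists in this 1 peak set.

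Promoter shares of 3 heart lists did not differ from other genes past the threshold. Fetal hormone and stress genes had 8 of 10 (adjusted p = 0.125, Fisher's exact test), with Cited2 at 43.3, Hspb7 at 34.9 and Fhl2 at 25.4. The natriuretic peptide genes Nppb and Nppa had 16.8 and 5.44, and Acta1 and Xirp2 had no promoter peak. Smooth muscle and pericyte genes had 10 of 13 (adjusted exact p = 0.115), with Smtn at 26.7, Cspg4 at 24.8 in a peak that also reaches another gene's promoter, and Abcc9 at 15.4, while Myh11, Mylk and Lmod1 had none. Epicardial genes had 6 of 12 (adjusted exact p = 1), with peaks at Tbx18 (14.5), Tcf21 (10.6) and Wt1 (4.90), and none at the retinaldehyde dehydrogenase genes Aldh1a1 and Aldh1a2 or at Bnc1. The epicardial share was above that of other genes in the single lists (75% in replicate 2, 58.3% in replicate 1) and in the pooled list (66.7%), and below it past the threshold among replicated peaks with a signal value at or above the median.

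Genes of blood, nerve and other organs mostly lacked promoter peaks. Erythroid genes had 3 of 18 (Tfrc 29.5, Tal1 12.4, Epor 4.02), with none at Hbb-y, Alas2, Epb42 or Ermap in the replicated list. Macrophage and leukocyte genes had 2 of 18 (Spi1 4.08, Laptm5 3.50), with none at Adgre1, Aif1 or C1qa. Neural crest, neuron and glia genes had 3 of 15, with Hand2, which is also a cardiac factor, at 35.7, Elavl4 at 10.2 and Ednrb at 6.35, and none at Dbh, Foxd3 or Gap43. Skeletal muscle genes had 6 of 22 (Mylpf 10.3 in a peak that also reaches another gene's promoter, Tnni2 8.16, Tnnt3 6.90), with none at Myod1, the myogenic master regulator gene, or at Cacng1, Chrna1 and Chrng. Liver genes had 3 of 22, with none at Alb, Afp or Ahsg; Apoa2 had 18.4 and Foxa3 5.90 in peaks that also reach another gene's promoter, and Nr1h4 had 4.24. The Apoa2 promoter peaks of the single lists had signal values of 4.68 and 3.71. Of the genes named here and above as lacking a replicated promoter peak, Epb42 had one in both single lists, and Xirp2, Lmod1, Aldh1a1, Aldh1a2, Bnc1, Gap43 and Mcm3 had one in 1 of them.

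Forebrain genes had 2 of 22 promoter peaks (Bcl11b 5.79, Satb2 4.86), with none at Foxg1, Dlx1, Dlx2 or Dlx5. Lung and gut epithelium genes had 2 of 18 (Elf3 6.51, Vil1 1.99), with none at Cdh1, Cdx1 or Cdx2. Limb and posterior patterning genes had 1 of 18 (Msx2 4.12), with none at Alx4, En1 or Fgf10, and pluripotency and germline genes had 2 of 18 (Esrrb 12.6, Dazl 6.57), with none at Pou5f1, Ddx4, Dppa2 or Dppa3. All 9 of these lists were lower than other genes. The adjusted p was 4.59e-05 for forebrain, 7.99e-05 for limb, 0.000292 for liver and 0.000362 each for leukocytes, lung and gut, and pluripotency. It was 0.00227 for erythroid cells, 0.0117 for neural crest, neurons and glia and 0.0198 for skeletal muscle (Fisher's exact test). The erythroid call was lost with the pooled list, and the skeletal muscle call was lost without replicate 1.

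**Figure D2:**
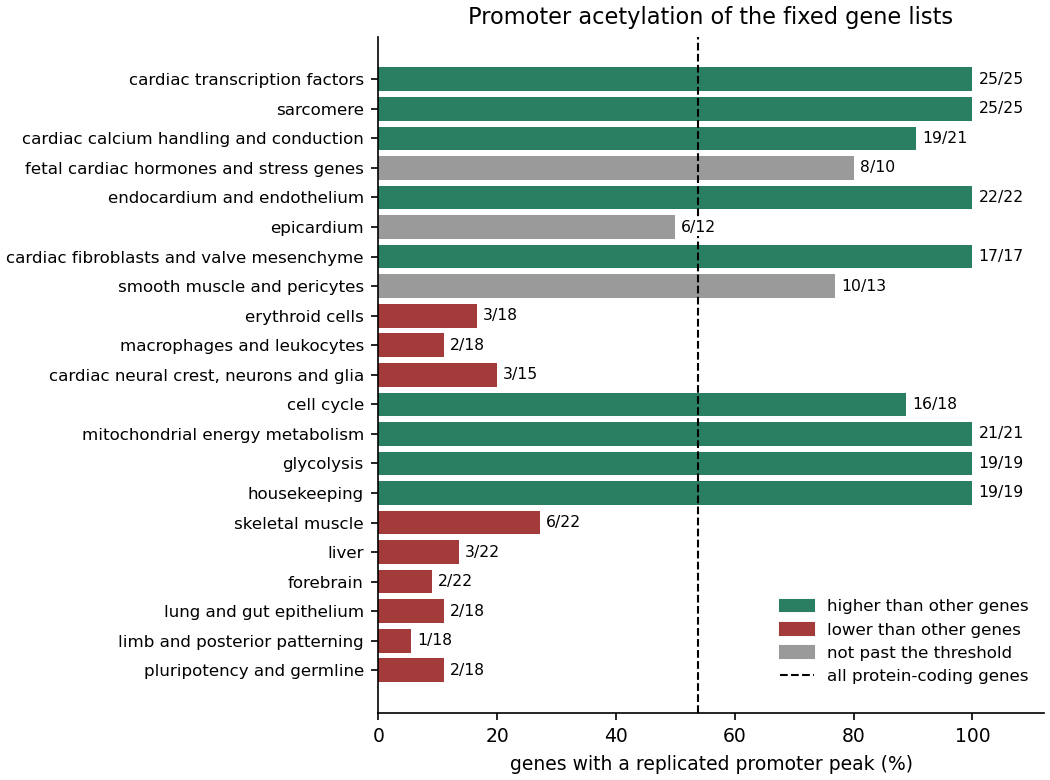
Percent of the genes of each list with a replicated promoter peak (bars, with counts beside them); green bars were higher and red bars lower than other protein-coding genes past an adjusted p of 0.05, grey bars were neither, and the dashed line marks all protein-coding genes (53.8%). All 25 cardiac transcription factor genes had a promoter peak, against 2 of 22 forebrain genes.

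Many heart muscle genes lay in wide acetylated domains. Around Gata4, 47.8 kb within 10 kb of its transcript starts were covered by replicated peaks. The corresponding lengths were 22.0 kb for Myh6, 21.2 kb for Tbx5, 20.0 kb for Myh7, 18.9 kb for Hand2, 18.6 kb for Nkx2-5, 16.7 kb for Tnnt2 and 11.7 kb for Actc1. Among genes with a promoter peak the median was 2311 bp, and their 95th percentile was 9370 bp. The windows around all transcript starts of a gene were joined, so a gene with many starts, such as Gata4, has a longer window. These lengths were therefore not compared at like window size. Shorter lengths were found at Hey2 (8.22 kb), Wt1 (7.10 kb), Pecam1 (3.66 kb), Nppb (3.49 kb), Nppa (2.46 kb) and Isl1 (0.28 kb). The Myh7 promoter peak ran over 18184 bp on chromosome 14 from 54981255 to 54999438 (mm10), across the 5′ end of the gene, and the Myh6 promoter peak over 12708 bp from 54960162 to 54972869. The Gata4 promoter peak spanned 16138 bp on the same chromosome (63242134 to 63258271), the Hand2 peak 14403 bp on chromosome 8 (57316450 to 57330852) and the Nkx2-5 peak 11090 bp on chromosome 17 (26835126 to 26846215).

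**Figure D3:**
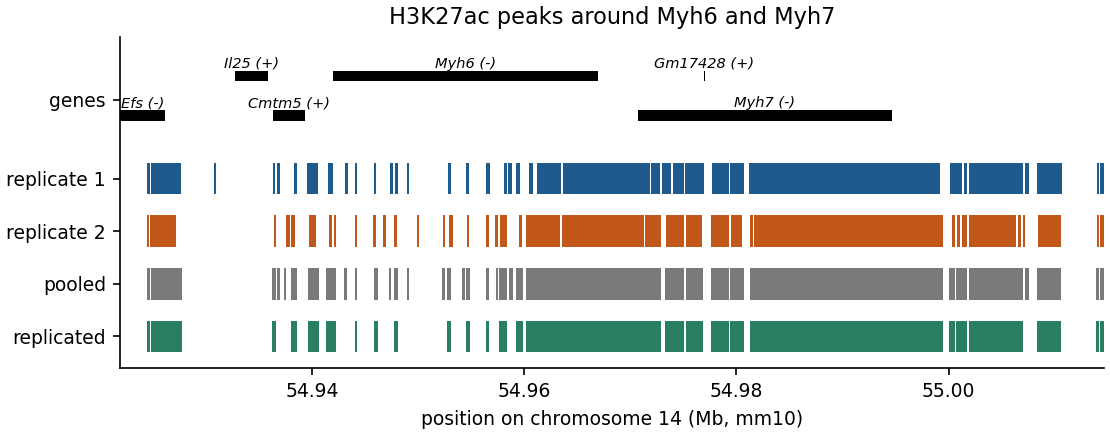
Peaks of the replicate 1, replicate 2, pooled and replicated lists (coloured blocks) and protein-coding genes with their strands (black bars) on chromosome 14 from 54921921 to 55014626 (x axis, Mb, mm10). The widest replicated peak of the region shown, 18184 bp, lay over the start of Myh7, and the region held 38 peaks of replicate 1, 39 of replicate 2 and 26 replicated peaks.

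Sarcomere genes had a geometric mean of 11.4 kb of covered sequence, 4.63 times that of random genes with a promoter peak (2.39 kb), and 24 of 25 lay above the median of such genes. The ratio was 3.47 for cardiac transcription factors (8.53 kb, 23 of 25 above the median), 3.35 for calcium handling and conduction (8.23 kb, 19 of 19), 2.91 for fetal hormone and stress genes (7.16 kb, 8 of 8) and 2.81 for glycolysis (6.90 kb, 19 of 19). Endothelial genes had a ratio of 2.03 (17 of 22), fibroblast and valve genes 1.88 (16 of 17) and housekeeping genes 1.51 (13 of 19). Each comparison used 100000 random draws of genes. The adjusted permutation p was 5e-05 for sarcomere, cardiac factors, calcium handling and glycolysis, where the unadjusted p of 1e-05 is the smallest that the draws can give. It was 0.000667 for the fetal list, 0.0002 for endothelium, 0.00283 for fibroblasts and valve mesenchyme and 0.0497 for housekeeping genes, whose ratio was 1.53 without replicate 1, 1.51 with peaks of −log10 q of at least 2 and 1.48 with draws matched on gene density, each just short of the threshold (adjusted permutation p = 0.0606, 0.0512 and 0.0545). The ratio of cardiac transcription factors ranged from 1.96 with a window of one size around the 5′ end to 12.4 against all protein-coding genes, and that of sarcomere genes from 3.53 to 16.5, with both calls kept.

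Forebrain and lung and gut genes were narrower (ratios of 0.182 and 0.236, adjusted permutation p = 0.00562 and 0.0214), each from 2 genes with a promoter peak. With a window of one size around the 5′ end of the gene the ratios hardly moved (0.218 and 0.234), but neither passed the threshold (adjusted permutation p = 0.0520 and 0.0574). The lung and gut call was lost in 5 of 8 alternatives, also without replicate 1, with the pooled list, within 20 kb and against all protein-coding genes, and its ratio reached 0.637. Ratios of the other lists did not pass the threshold. They were 1.44 for mitochondrial genes (adjusted permutation p = 0.0655, past the threshold within 5 kb, within 20 kb, without replicate 2 and against all protein-coding genes), 2.33 for neural crest, neurons and glia, 1.40 for smooth muscle, 1.30 for skeletal muscle, 1.21 for erythroid genes, 0.963 for epicardium, 0.849 for liver, 0.794 for leukocytes, 0.748 for the cell cycle and 0.691 for pluripotency. The neural crest ratio rests on 3 genes, among them the cardiac factor Hand2. Erythroid and liver ratios rest on 3 genes each too, and leukocyte and pluripotency ratios on 2 each. The leukocyte ratio was 0.286 without replicate 1 and the liver ratio 0.296 against all protein-coding genes, both past the threshold. Limb genes had only Msx2 with a promoter peak and were not tested in the main comparison. All 18 entered the test against all protein-coding genes.

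**Figure D4:**
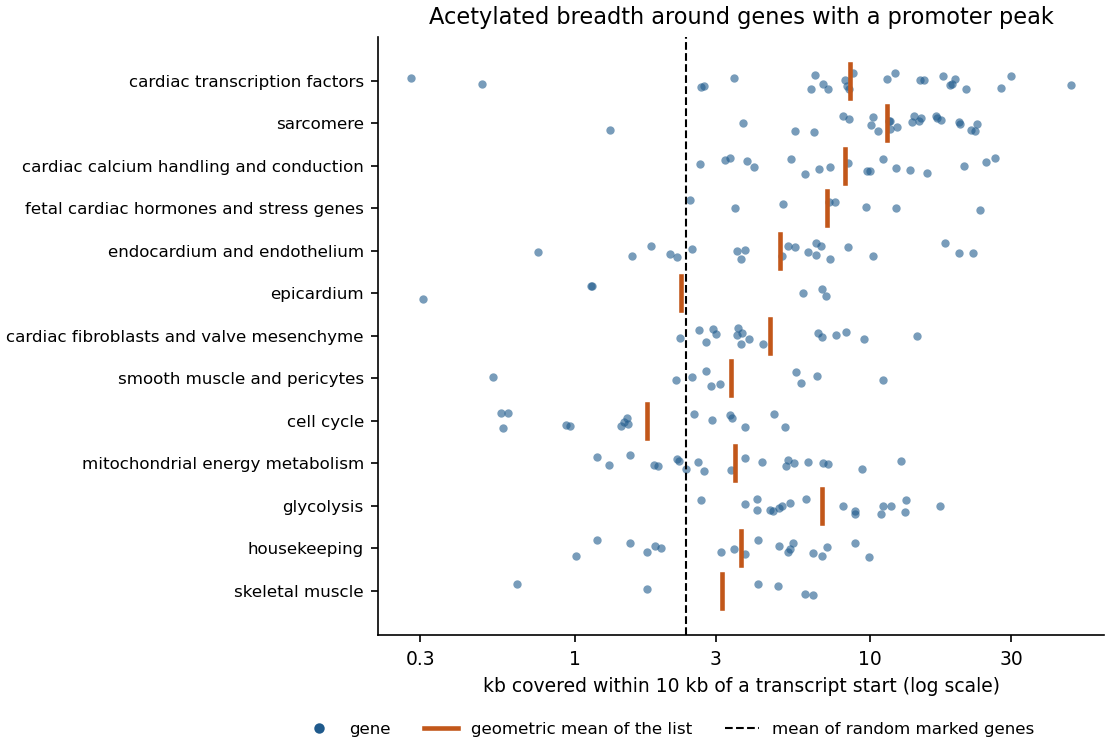
Kilobases covered by replicated peaks within 10 kb of a transcript start (x axis, log scale) for each gene with a promoter peak (points) in lists with at least 5 such genes; orange bars mark the geometric mean of each list and the dashed line that of random genes with a promoter peak (2.39 kb). The sarcomere list had the highest geometric mean, 11.4 kb.

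The gene with the most covered sequence was Tns1, which encodes the focal adhesion protein tensin 1, with 78.7 kb. It was followed by Mical2, an actin-oxidising enzyme gene, with 54.4 kb, Dab2ip with 47.9 kb, Gata4 with 47.8 kb and Actn4, a non-muscle actinin gene, with 44.6 kb. Rbpms, an RNA-binding protein gene, had 40.7 kb, Pitpnm2 37.1 kb, Rara, a retinoic acid receptor gene, 35.0 kb, Zmynd8 34.7 kb and Shroom3 32.8 kb. Genes with many transcript starts have longer windows, 144 kb for Tns1 and 60.6 kb for Gata4, which raises the length that can be covered.

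Distal peaks were dense around heart genes. Those within 10 kb of a transcript start count in the breadth as well, and the clusters below join the same distal peaks. The comparisons of breadth, distal peaks and clusters are therefore not independent. Within 50 kb of the 5′ end, Atp2a2 had 25 distal peaks, Nkx2-5 had 25, Slc8a1 had 23, Gata4 and Tbx5 had 20 each, and Myh6 and Tnnt2 had 18 each, where the median gene with a promoter peak had 3. Such counts depend on how a list splits a domain. In the region shown around Myh6 and Myh7, 38 peaks of replicate 1 covered 55.2 kb and 26 replicated peaks covered 56.5 kb. Sarcomere genes had a mean of 11.4 distal peaks against 3.76 for random genes with a promoter peak (22 of 25 above the median), calcium handling and conduction genes 10.2 (16 of 19) and cardiac transcription factors 10.1 (19 of 25), each with an adjusted permutation p of 6.67e-05. Fetal hormone and stress genes had a mean of 8 (7 of 8, adjusted permutation p = 0.0268) and endothelial genes 7.41 (16 of 22, adjusted permutation p = 0.0007). Nppa had 6, Nppb 5, Actc1 3, Hey2 3 and Isl1 none.

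Fibroblast and valve genes had a mean of 6.06 distal peaks (adjusted permutation p = 0.0561), which passed the threshold without replicate 1 and in 3 other alternatives. Their difference from random genes was 2.30 in the main comparison and 1.89 to 4.96 over the alternatives. No other list passed in the main comparison. Within 25 kb neural crest, neurons and glia (adjusted permutation p = 0.0430) and glycolysis (0.0259) passed, and against all protein-coding genes glycolysis (0.0150) and housekeeping (0.0282) did, each with more distal peaks. The neural crest, neuron and glia call rests on 3 genes with a promoter peak, among them the cardiac factor Hand2. The mean was 8.33 for neural crest, neurons and glia, 8 for leukocytes, 5.8 for smooth muscle, 5.05 for glycolysis, 4.74 for housekeeping, 4.67 for skeletal muscle, 4.33 each for erythroid and liver genes, 3.86 for mitochondrial genes, 3.31 for the cell cycle, 3 for forebrain, 2.5 for epicardium and 2 each for lung and gut and for pluripotency. Neural crest, erythroid and liver means rest on 3 genes each. Leukocyte, forebrain, lung and gut, and pluripotency means rest on 2 each.

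The largest cluster of distal peaks covered 128 kb in 98 peaks on chromosome 11 from 88373890 to 88730310 and contained the 5′ end of Msi2, a gene of a Musashi RNA-binding protein. The next were at Tns1 (92.1 kb on chromosome 1, 73902547 to 74084953), Zmiz1 (90.8 kb on chromosome 14, 25443253 to 25647036), Rbpms (90.3 kb on chromosome 8, 33772965 to 33924345) and Rbm20, a regulator of titin splicing (85.1 kb on chromosome 19, 53647971 to 53831626). Igf2r (72.9 kb), Wasf2 (68.6 kb), Smad6, an inhibitor of BMP signalling (63.9 kb), Nfib (63.8 kb, inside the gene and 188 kb from its 5′ end) and the type IV collagen gene Col4a1 (61.1 kb) completed the 10 largest. Joining the 49682 distal peaks gave 19387 clusters, 9689 of them a single peak. The 194 clusters with the most covered bases held 13.6% of all distal peak bases, and 342 genes (1.56%) started within 50 kb of one.

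Among cardiac transcription factors 6 of 25 genes started within 50 kb of such a cluster (24% against 1.53% of other genes, adjusted p = 3.98e-05, Fisher's exact test). They were Nkx2-5, Gata4, Gata6, Irx4, Myocd and Tead1. Calcium handling and conduction genes had 4 of 21 (adjusted exact p = 0.00296), namely Ryr2, Atp2a2, Jph2 and Camk2d, a call that was lost when peaks were joined over 5 kb. The sarcomere list had Actn2 and Ldb3 (8%, adjusted exact p = 0.241), and passed the threshold in each single list (20%) and with joining over 25 kb (16%). Endothelium had Eng and Notch1 (adjusted exact p = 0.239), fibroblasts and valve mesenchyme Col1a1 and Meox1 (adjusted p = 0.198), the fetal list Fhl2, mitochondrial metabolism Ppargc1a and skeletal muscle Tnnt3. No gene of the other lists started near such a cluster. Genes outside the rule for named genes were listed here because the counts are small, after their values were seen.

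Consensus sites of TEAD factors, which act in the Hippo pathway, and the E-box CAGCTG, a site of basic helix-loop-helix factors in the list as the MYOD consensus, were denser in distal replicated peaks than in flanking control regions. The mean log2 ratio was 0.59 ± 0.10 (SD over 20 chromosomes) for TEAD, 0.61 ± 0.08 for the E-box and 0.33 ± 0.10 for AP-1, each higher on 20 of 20 chromosomes. ETS sites had 0.63 ± 0.25, NKX2 sites 0.12 ± 0.06 (19 of 20 chromosomes) and SOX sites 0.11 ± 0.06 (19 of 20), with the reversed SOX sequence at 0.19. GATA sites were less dense at −0.20 ± 0.06 and POU-SOX sites at −0.46 ± 0.15 (0 of 20 chromosomes higher for both). The reversed GATA and POU-SOX sequences were lower too (−0.40 and −0.37), and the reversed E-box, AP-1, ETS and NKX2 sequences were higher (0.32, 0.12, 0.27 and 0.06), so a difference in the same direction was also found without the motif. The ETS consensus holds a CG pair, which its reversed sequence lacks. The reversed POU-SOX and E-box sequences hold a CG pair, which their consensuses lack. For these the reversed sequence is not a full control for composition. The adjusted p of each of the 8 consensuses named so far was 2.25e-05 (two-sided sign permutation over chromosomes). It came from an unadjusted p of 1e-05, the smallest that the permutations can give. Chromosomes are parts of the same peak list, so p-values and SDs of the consensuses do not measure the spread between replicates. HNF1 sites were lower at −0.77 ± 0.78 (adjusted permutation p = 0.00122), from 17 sites in peaks and 53 in control regions, with the reversed sequence at −1.01, and lost the call in 4 of 6 alternatives.

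Peaks were richer in G and C (48.0%) than control regions (44.6%), and control regions of like GC content moved several consensuses. Against these, over 16575 peaks with 46.9% against 46.5% GC, TEAD had 0.53 ± 0.15 and AP-1 0.30 ± 0.20, with their reversed sequences at −0.08 and 0.17. The E-box fell to 0.29 ± 0.08 and was higher on 20 of 20 chromosomes. Its reversed sequence, which unlike the E-box holds a CG pair, had 0.31 ± 0.50 (13 of 20). That value rests on 303 sites in peaks and 285 in control regions, too few to tell whether composition accounts for the E-box value. NKX2 fell to 0.04 ± 0.07 (12 of 20 chromosomes higher), with its reversed sequence at −0.04 ± 0.07 (7 of 20). SOX had 0.06 ± 0.12 and its reversed sequence 0.20. POU-SOX had −0.15 ± 0.24 and its reversed sequence −0.38 ± 0.82, from 128 sites in peaks. The ETS call was lost (0.11 ± 0.47, adjusted permutation p = 0.355), and GATA turned to 0.08 ± 0.08 (17 of 20 chromosomes higher, adjusted permutation p = 0.00159). The reversed GATA sequence was at −0.07 ± 0.08 (2 of 20), opposite in direction to the consensus. MEF2, the site of myocyte enhancer factors, did not pass the threshold in the main comparison (−0.04 ± 0.11, adjusted permutation p = 0.139), where its reversed sequence was at −0.96 ± 0.11. The MEF2 consensus was higher on 20 of 20 chromosomes against control regions of like GC content (0.73 ± 0.18, adjusted permutation p = 4.5e-05), with its reversed sequence at −0.12 ± 0.19. MEF2 was lower past the threshold without replicate 1 (−0.23), without replicate 2 (−0.12) and within 200 bp of summits (−0.17).

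The remaining consensuses did not pass the threshold in the main comparison. The log2 ratio was 0.36 for RFX (29 sites in peaks), 0.23 for CTCF, 0.10 for HNF4, 0.09 for SRF, 0.01 for HAND, −0.07 for MEIS and −0.09 for T-box. Adjusted permutation p-values ran from 0.0947 for SRF to 0.651 for MEIS. The NEUROD consensus is the reverse complement of the HAND consensus and gave the same sites. Against control regions of like GC content SRF was higher past the threshold (0.23 ± 0.30), with its reversed sequence at −0.0027 ± 0.35. CTCF, HAND and T-box were lower there (−0.45 ± 0.76, −0.08 ± 0.07 and −0.22 ± 0.37). The reversed HAND and T-box sequences were as low or lower (−0.23 and −0.22). The CTCF value there rests on 114 sites in peaks and 171 in control regions. Its reversed sequence was at 0.16 ± 1.60, from 26 sites in peaks and 26 in control regions, too few to serve as a control. CTCF was higher past the threshold with control regions 5 kb away (0.30) and within 200 bp of summits (0.36). T-box (−0.18) and MEIS (−0.25) were lower past the threshold with control regions 5 kb away, and SRF was higher without replicate 2 (0.11).

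**Figure D5:**
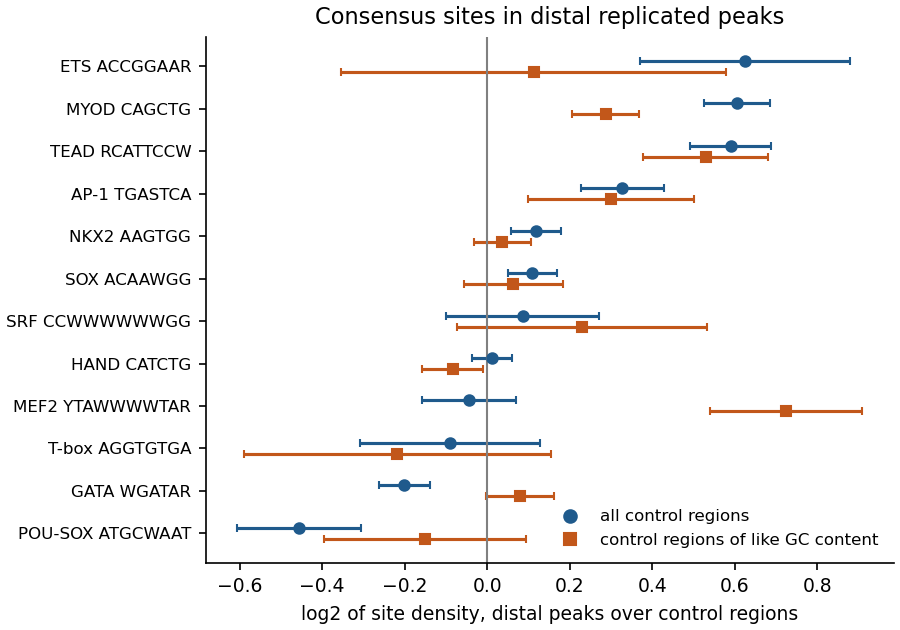
Mean log2 ratio of site density in distal replicated peaks over control regions (x axis) for consensuses with at least 1000 sites in peaks, with SD over 20 chromosomes as bars; circles used all control regions and squares those of like GC content. TEAD stayed at 0.59 and 0.53, while MEF2 moved from −0.04 to 0.73.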

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

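The breadth window of one size and the promoter shares with only the peaks shared with both single lists were chosen after the result was seen. Strength and width differences of promoter and distal peaks kept direction and call in 3 alternatives each. Of the 18 promoter share calls 16 kept direction and call under every alternative, as did 7 of 10 breadth calls, 5 of 5 distal peak calls, 1 of 2 cluster calls and 6 of 9 motif calls. The cause of the changes below was not tested unless stated. Depth is unknown, so its effect on weak peaks was not tested, and no paired analysis applied to 1 group.

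A looser or stricter overlap rule moved the sharing of replicates by construction. Peak thresholds moved it as well, for reasons that were not tested. With any shared base, replicate 1 shared 66.3% and replicate 2 67.4%, and 86.1% of replicated peaks were shared with both. With at least 50% of both peaks covered the shares were 41.2%, 37.5% and 53.5%. With −log10 q of at least 2 they were 62.1%, 66.1% and 75.1%, the pooled peaks kept were 66.9% and the Jaccard index was 0.574. With signal values at or above the median they were 71.0%, 70.9% and 89.9%. The Jaccard index was 0.598 with peaks within 1 kb joined. Ranked by −log10 q, the weakest deciles shared 24.0% and 27.9%.

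The promoter share of replicated peaks was 21.4% with 500 bp, 27.3% with 2.5 kb, 18.7% with 5′ ends only, 17.0% in the pooled list, 35.6% with signal values at or above the median, and 18.1% to 18.5% in single lists. The share of genes with a promoter peak was, in this order, 53.1%, 55.5%, 50.9%, 56.7%, 47.7%, and 55.0% to 55.4%. The epicardial promoter share turned above other genes with the pooled list (66.7%) and in single lists (58.3% to 75%).

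Lists narrower than random genes numbered 1 with 20 kb, 1 with the pooled list, 1 with −log10 q of at least 2, 4 against all protein-coding genes and 0 with a window of one size. Breadth ratios that turned direction were, with 20 kb, leukocytes 1.33 and liver 1.11, and with the pooled list erythroid genes 0.569. Single lists gave erythroid 0.608 to 0.720, skeletal muscle 0.729 to 0.951 and leukocytes 0.286 to 1.11. With a window of one size epicardium had 1.09 and liver 1.02. Against all protein-coding genes, which lets genes without a promoter peak count, the ratio was 0.322 for erythroid genes (adjusted permutation p = 0.00499), 0.447 for neural crest, neurons and glia, 0.553 for skeletal muscle and 2.15 for the cell cycle.

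Lists with more distal peaks than random genes numbered 8 with 25 kb and 8 against all protein-coding genes. Differences in distal peaks that turned direction, none past the threshold, were 0.248 for epicardium with 25 kb. With 100 kb they were −0.331 for erythroid, −1.30 for mitochondrial and 1.64 for lung and gut genes. With the pooled list erythroid genes had −3.24 and liver −1.65. Single lists gave erythroid −2.75 to −1.16, cell cycle −0.755 to 0.202 and mitochondrial −0.114 to 0.593. Against all protein-coding genes erythroid had −1.10, leukocytes −0.146, cell cycle 0.457, skeletal muscle −0.325, liver −1.33 and lung and gut 0.0668.

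Lists near the largest clusters numbered 1 with joining over 5 kb. Shares near such clusters that crossed those of other genes, none past the threshold, were 13.3% for neural crest, neurons and glia and 10.5% each for glycolysis and housekeeping with 5 kb, and 8.33% for epicardium and 0% for mitochondrial genes with 25 kb. Single lists gave 0% to 5.56% for erythroid, cell cycle, and lung and gut genes, 0% to 10.5% for glycolysis, 5.26% for housekeeping in both and 0% to 13.3% for neural crest, neurons and glia. Of the 194 largest clusters 147 overlapped one of the largest with 5 kb, 119 with 25 kb, 183 without replicate 1 and 182 without replicate 2.

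With control regions of like GC content 5 consensuses were lower, HAND and NEUROD being the same sites. Log2 ratios that turned direction there were 0.73 for MEF2, 0.080 for GATA, −0.083 for HAND and NEUROD, −0.45 for CTCF, −0.014 for HNF4 and −0.22 for RFX. Of these MEF2, GATA, HAND and CTCF passed the threshold, and that comparison kept 16575 of 45221 peaks. MEF2 had 0.011 with control regions 5 kb away. Within 200 bp of summits SRF had −0.049 and HAND and NEUROD −0.0022. Single lists gave −0.0026 to 0.11 for SRF and −0.042 to 0.00061 for MEIS.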

Other observations

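The gene families and chamber genes, the tests of the families, of the replicated peaks and of the X chromosome, and the tests of MEF2 values between settings were chosen after the result was seen, while the control regions of like GC content and the reversed sequences were planned. Genes are not independent replicates, so the p-values below describe these families in this 1 peak set. Hox genes of paralog groups 6 to 13 lacked a replicated promoter peak. None of the 16 Hox genes of groups 9 to 13 (adjusted p = 1.17e-05) and none of the 8 of groups 6 to 8 (adjusted p = 0.00415) had a replicated promoter peak, while 4 of 15 of groups 1 to 5 had one (Hoxb2, Hoxa1, Hoxb4 and Hoxa2; adjusted p = 0.0665, Fisher's exact test over 30 families). Of the WNT ligand genes 2 of 19 had one, Wnt5a and Wnt5b (adjusted exact p = 0.000266). Voltage-gated potassium channel genes had 7 of 40 (adjusted exact p = 1.02e-05), among them the cardiac Kcnh2 and Kcnq1, and voltage-gated sodium channel genes 2 of 14, Scn2b and the cardiac Scn5a (adjusted p = 0.00946). Keratin genes had 5 of 49, protocadherin genes 13 of 69, cytochrome P450 genes 16 of 100, olfactory receptor genes 6 of 1093, vomeronasal receptor genes 2 of 327 and beta-defensin genes 0 of 42, all lower than other genes past the threshold. Higher shares were found for cytosolic ribosomal protein genes (75 of 75), complex I subunit genes (36 of 36), proteasome subunit genes (34 of 39, adjusted exact p = 3.6e-05), mitochondrial carrier genes (38 of 47, adjusted p = 0.000382), zinc finger genes named Zfp (276 of 365) and Krüppel-like factor genes (14 of 17, adjusted p = 0.0453). T-box genes (6 of 13), SOX genes (13 of 19), forkhead genes (20 of 44), collagen genes (22 of 44), laminin genes (7 of 11) and integrin genes (14 of 26) did not differ from other genes past the threshold.

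Among genes used more in ventricles, 20.1 kb were covered around Myl2, 20.0 kb around Myh7 and 5.08 kb, the shortest, around Mpped2, with a median of 12.2 kb over 11 genes. Genes used more in atria had a median of 4.19 kb over 15 genes, from 0 kb at Sln and 2.46 kb at Nppa to 14.6 kb at Myl4 and 21.2 kb at Tbx5. The genes of both sets were picked with their values in view, so no test applies and the medians hold for these genes alone. Whole hearts were used, so the shares of atrial and ventricular tissue behind these values are unknown.

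Of the replicated peaks, 9221 were not shared with both single lists, 5218 of them with replicate 1 only and 3665 with replicate 2 only. A looser overlap rule does not account for them, since 3.20% touched peaks of both lists by at least 1 base. A further criterion tied to peak strength stays a candidate explanation. Among pooled peaks not shared with both, the share kept in the replicated list was 64.9 percentage points higher in the highest than in the lowest decile of −log10 q (67.0% against 2.02%), but it dipped from 3.03% to 2.87% between neighbouring low deciles. No biological explanation was tested, since the selection is a processing step.

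MEF2 sites, which are rich in A and T, were not denser in distal peaks than in flanking regions although MEF2 factors act in heart muscle. With control regions of like GC content the mean log2 ratio rose by 0.77, more than the SDs of both comparisons together, so the higher GC content of the peaks may have hidden a higher density. The comparison also kept a smaller set of 16575 peaks, and the effect of that selection was not tested. Base composition alone does not account for the matched value, since the consensus exceeded its reversed sequence by 0.85, and over all 45221 peaks the reversed sequence (−0.96) was below the consensus (−0.04) too. No biological explanation was tested, because the design has 1 group.

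The X chromosome held 4.52 distal replicated peaks per Mb, where autosomes held 15.6 to 28.5, and 38.4% of its genes had a promoter peak, where autosomes had 44.3% to 62.3%. Fewer genes do not account for the fewer distal peaks. The X chromosome had 0.815 distal peaks per gene (autosomes 1.31 to 3.97) and 2.12 per gene with a promoter peak (autosomes 2.96 to 6.65). Nor does repeat sequence, since the X chromosome had 8.88 distal peaks per Mb outside repeats (autosomes 24.6 to 42.2). These comparisons do not cover the lower share of genes with a promoter peak. Promoter peaks of marked genes on the X chromosome had a median signal value of 10.4, below every autosome (12.4 to 14.7). The lower signal may place more of its weak sites under the peak threshold, which was not tested. The pools held both sexes and the scale of the signal value is not stated. Whether the presence of 1 copy in males plays a part can therefore not be told. The design has no groups by sex, so no biological explanation was tested.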
